A study of Mus musculus with 12 samples.

How the data were processed

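The 12 libraries came from cortex of male mice, with 4 WT, 2 5xFAD, 2 Tet1(+/-) and 4 FAD/Tet1(+/-) animals, and the labels name each as a "biol" replicate. Per the labels, RNA was extracted with TRIzol, selected with the NEBNext Poly(A) module and made into libraries with the NEBNext Ultra II Directional kit. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.36, aligned them to mm10 with STAR 2.7.0f and tested genes with DESeq2. The version of DESeq2, the counting program, its annotation release and its strand setting are not given in the sources used here.

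The deposited files held raw counts per library, as whole numbers per Ensembl gene, and these counts were the input of every test. The authors also deposited a table of variance-stabilised expression (VST, log2-like) for 21283 genes, which was checked against the counts and used for no test. The deposited results tables, which per the file headers follow the DESeq2 format, give a mean signal (size-factor normalized counts averaged by the authors over the libraries), a log2 fold change with its standard error, a score (Wald statistic), a p-value and an adjusted p-value. They are quoted as the submitters' values. In their table of 5xFAD and FAD/Tet1(+/-), the sign of the fold was taken from the counts and is FAD/Tet1(+/-) minus 5xFAD.

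Of the gene identifiers, 42462 were named from the GENCODE M21 annotation (GRCm38, which is mm10), 36 from the authors' table alone, and 934 have no symbol. Reads were not realigned. Genes that share sequence with near-identical copies, or that overlap a gene on the other strand, are uncertain to that extent.

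Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the genotype as group, which left 16975. Library sizes were scaled by trimmed mean of M-values (TMM), and 1 quasi-likelihood model with robust dispersion was fitted to the 12 libraries with a mean for each genotype. Two-sided quasi-likelihood F-tests gave the p-values, which were adjusted over the genes tested by Benjamini-Hochberg, and an adjusted p under 0.05 is the threshold throughout. Unless another tool is named, each adjusted p of a gene in the report is from this model. Confidence intervals are at 95%. Counting intervals, for genes with under 10 counts in a group, are exact binomial and cover counting error alone, with no spread between animals. CPM values are TMM-scaled, and log2 CPM for scores used a prior count of 2.

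The 7 comparisons were 5xFAD against WT, Tet1(+/-) against WT, FAD/Tet1(+/-) against Tet1(+/-), against 5xFAD and against WT, the interaction of the genotypes, and the average 5xFAD effect over both Tet1 states. The groups, the comparisons, 28 gene lists and the other settings given at the end were chosen before the data were examined. The lists were disease-associated microglia, homeostatic microglia, complement, antigen presentation, interferon response, cytokines and NF-kB, reactive astrocyte, astrocyte, myelin, oligodendrocyte precursor, excitatory neuron, inhibitory neuron, endothelial, mural and fibroblast, choroid plexus, erythroid, striatum, hippocampus and thalamus, immediate-early, synaptic, DNA methylation machinery, amyloid and tau processing, cholesterol synthesis, lysosome, stress and unfolded protein, oxidative phosphorylation, cytosolic ribosome and mitochondrially encoded genes.

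Lists were tested with camera of limma 3.58.1, which compares the genes of a list with all other genes, at a preset correlation between genes of 0.01 and with the correlation estimated from the data. Adjustment was over the 28 lists of a comparison. The fry test asks whether the genes of a list move on balance in one direction, and its mixed p-value whether they move in either, and neither compares them with other genes. Members of a list are counted as passed after adjustment over all genes tested, and separately after adjustment over the members of that list alone.

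Named genes were the targeted genes, the 10 largest rises and 10 largest falls of a comparison among genes past the threshold, and up to 4 members of each list with the smallest p-values. Rises and falls needed an average log2 CPM of at least 1, a symbol that is not a predicted or clone name and, except for the interaction and the average effect, groups whose CPM values do not overlap. A gene named for 1 comparison could be given for the others. Genes of the submitters' tables and tissue markers outside the lists were named after their values were seen.

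Other settings fixed at that time were the size factors of DESeq2, no filter on low counts, DESeq2 1.42.0 with Wald tests on the same genes, a threshold of 0.1, the replicate number as a block, the sample-number range as a block (179 to 182, 270 to 283, 296 to 299 and 344 to 347, the numbers per the labels), a fit to the compared groups alone, and each library left out in turn. Added after the data were seen were the omission of 5xFAD 1 and FAD/Tet1(+/-) 1, covariates from striatal and choroid plexus markers, and a covariate from 17 markers of amygdala and hypothalamus. Libraries were also split into other groups of the same sizes and refitted. No library was left out of the main fit, and values from fits without a library are named as such.

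The procedure was tested on simulated data with 200 changed genes among 16975. At a 2-fold change it recovered 67.2% for 5xFAD against WT, 64.2% for Tet1(+/-) against WT, 64.2% for FAD/Tet1(+/-) against 5xFAD, 73.1% for FAD/Tet1(+/-) against WT, 46.3% for the interaction and 79.1% for the average effect, and at 1.5-fold 47.8%, 37.3%, 38.8%, 52.2%, 7.46% and 58.2%. False calls were 2.27% to 8.45% of the calls. The simulated genes were independent of each other and held no difference in dissected tissue, so these rates need not hold for the real libraries. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. Some results for single genes are not reported here. Reads, genotype of the Tet1 allele, protein and DNA methylation were not analysed here.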

Results

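Poly(A) RNA from the cortex of 12 male mice was sequenced in 4 genotypes: wild type (WT, n = 4), 5xFAD (n = 2), Tet1(+/-) (n = 2) and FAD/Tet1(+/-) (n = 4). 5xFAD mice carry transgenes with mutations of familial Alzheimer's disease under the mouse Thy1 promoter, and TET1 is an enzyme that oxidises 5-methylcytosine in DNA. The comparisons ask what the transgenes change in cortex with intact Tet1 and in mice labelled Tet1(+/-), and whether the Tet1 genotype alters that response. The total counts of WT 1 to WT 4 were 17885536, 19000983, 17069475 and 17995858. Those of 5xFAD 1 and 2 were 19390859 and 19531125, and those of Tet1(+/-) 1 and 2 were 16639151 and 15961931. FAD/Tet1(+/-) 1 to 4 held 17058200, 17590924, 17151225 and 14912607 counts. The filter on low counts left 16975 genes, which were tested, with a common biological coefficient of variation of 12.48% between replicates. Mitochondrially encoded genes took 4.111% to 6.384% of the counts. The labels call the replicates "biol", and the p-values measure the spread between such animals, with no repeat of a library.

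The targeted genes were read first as a check of the labels. Thy1 (ENSMUSG00000032011, GRCm38 chromosome 9, 44043384 to 44048579, + strand), whose regulatory and untranslated sequence drives the transgenes, read 674 ± 49 CPM (counts scaled to library size, mean ± SD) in WT (n = 4) and 1700 ± 2.66 in 5xFAD (n = 2). In Tet1(+/-) it read 690 ± 31.7 (n = 2), and in FAD/Tet1(+/-) 2150 ± 276 (n = 4). It was higher in each of the 6 libraries with the transgenes (1700 to 2560 CPM) than in each of the 6 without (607 to 725 CPM). Its rise was 2.53-fold in 5xFAD over WT (log2 1.34, SE 0.102, edgeR adjusted p = 3.83e-05) and 3.12-fold in FAD/Tet1(+/-) over Tet1(+/-) (log2 1.64, SE 0.114, adjusted p = 1.19e-05). Thy1 was 1.26-fold higher in FAD/Tet1(+/-) than in 5xFAD, with a log2 interval of 0.107 to 0.564. By edgeR the unadjusted p was 0.0071 and the adjusted p 0.606. Each FAD/Tet1(+/-) library (1990 to 2560 CPM) was above both 5xFAD libraries (1700 and 1710). The mouse gene App (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766, - strand) encodes the amyloid precursor protein. App read 1630 ± 188 CPM in WT and 1580 ± 55.5 in 5xFAD, with an adjusted p of 0.893. Tet1 (ENSMUSG00000047146, chromosome 10, 62804570 to 62908996, - strand) read 13.7 ± 1.37 CPM in WT, 12.6 ± 0.825 in 5xFAD, 12 ± 0.568 in Tet1(+/-) and 13.2 ± 1.17 in FAD/Tet1(+/-). Averaged over both transgene states, its level in mice labelled Tet1(+/-) was 0.958 of that with intact Tet1, with a 95% interval of 0.843 to 1.09. The labels do not give the type of Tet1 allele, so the gene total does not test that label. Thy1, App and Tet1 are annotated as protein coding. Tet1 and App overlap other annotated genes, whose strand was not looked up. Reads of an overlapping gene on the other strand count for them if strands were not kept apart.

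**Figure D1:**
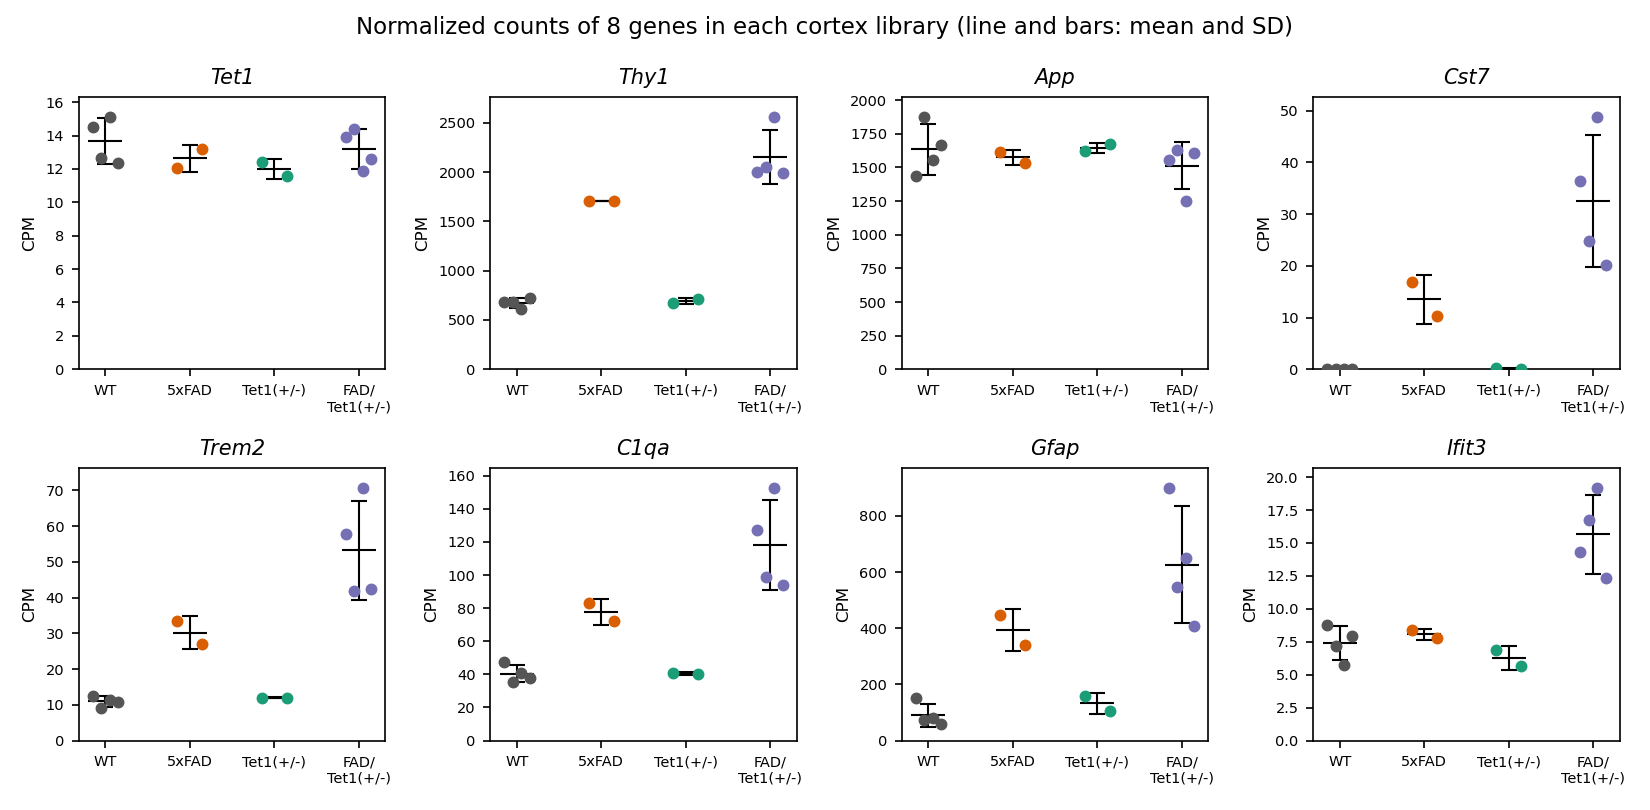
CPM (y axis) of 8 genes in each of the 12 libraries, by genotype on the x axis, with each library as a point and the group mean and SD as a line with bars. Thy1 lay between 1700 and 2560 in the libraries with the transgenes and between 607 and 725 in the others, while the Tet1 values of the 4 genotypes overlapped.

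Markers of tissue that borders the neocortex differed between libraries. Ttr, the thyroxine carrier made in bulk by choroid plexus, read 1040 CPM in 5xFAD 1 and 532 in FAD/Tet1(+/-) 1, against 3.66 to 27.8 in the other 10 libraries. Drd2, a dopamine receptor of striatal projection neurons, read 52.6 CPM in WT 3 and 17.1 in WT 1 but 0.267 in WT 2 and 0.797 in WT 4. Mbp, the myelin basic protein gene, read 2910 CPM in WT 3 and 1130 to 1620 in the other WT libraries. The mean of 17 markers of amygdala and hypothalamus was 1.544 log2 units above the WT mean in WT 1 and between -0.781 and -0.283 in the other 3. In the same units it was 1.629 and 2.058 in the 5xFAD libraries, 1.599 and 0.881 in Tet1(+/-), and -0.203 to 1.144 in FAD/Tet1(+/-). These 17 markers were listed after some of their values had been seen.

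**Figure D2:**
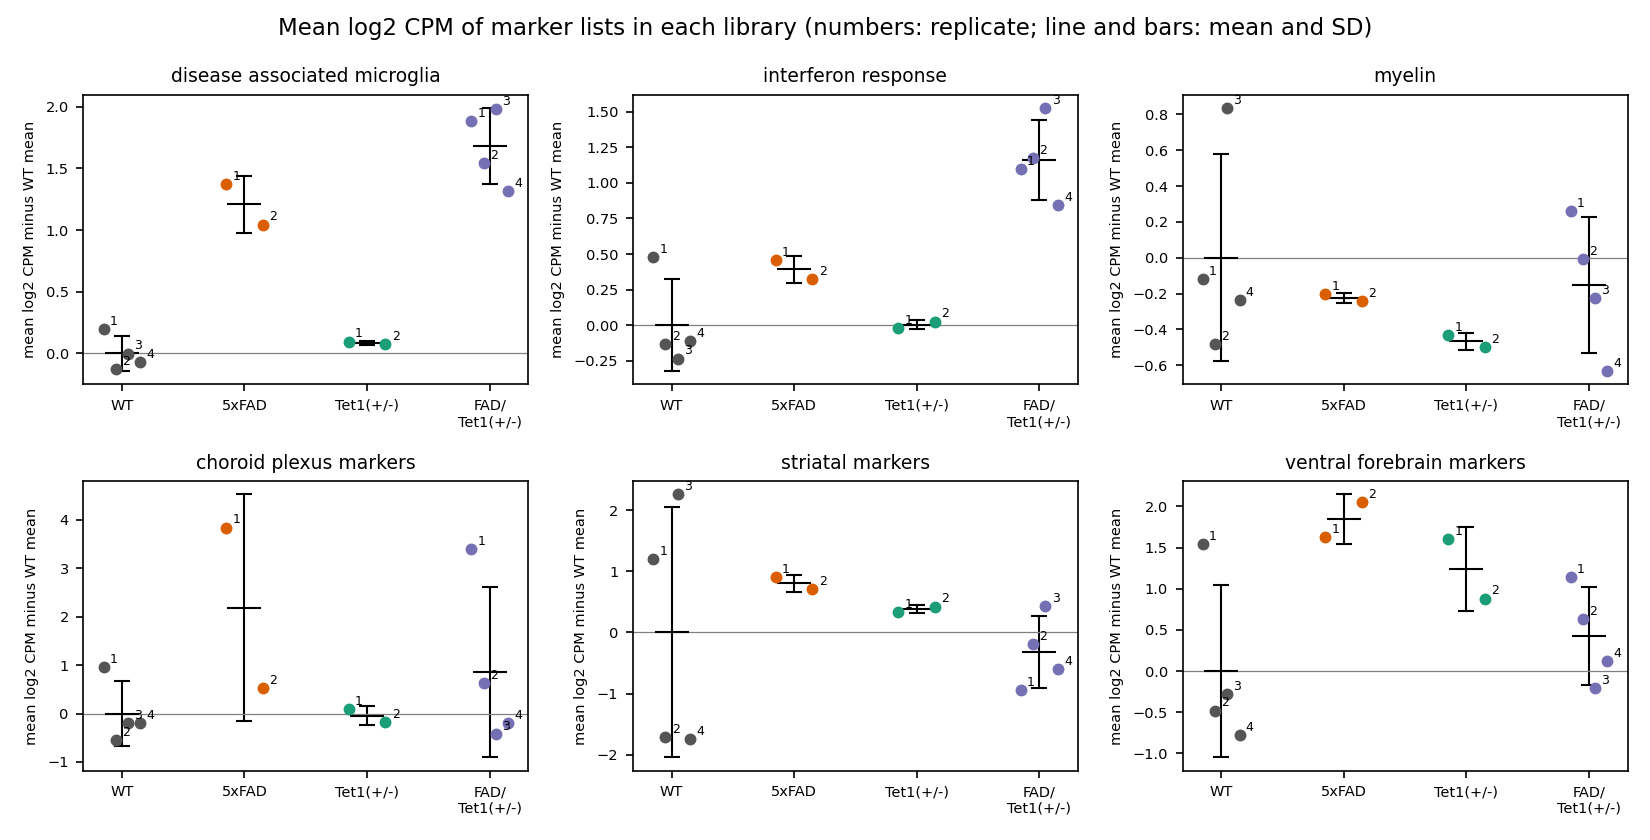
Mean log2 CPM of the members of 6 gene lists in each of the 12 libraries, minus the WT mean (y axis), by genotype on the x axis; each point is a library with its replicate number, and lines with bars give mean and SD. The choroid plexus score was 3.839 in 5xFAD 1 and 3.39 in FAD/Tet1(+/-) 1, and the striatal score of the WT libraries ran from -1.742 to 2.255.

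In 5xFAD cortex compared with WT (2 against 4 animals), the largest rises among single genes past the threshold were in genes of activated microglia. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944, + strand), which encodes the cysteine protease inhibitor cystatin F, rose 214-fold (log2 7.74, SE 0.669, adjusted p = 0.00106). It rests on 534 counts in 5xFAD and 4 in WT, a depth-adjusted ratio of 241 with a counting interval of 93.5 to 887. Itgax (ENSMUSG00000030789, chromosome 7, 128129547 to 128150657, + strand), the integrin CD11c, rose 30.1-fold (SE of the log2 change 0.451). Clec7a (ENSMUSG00000079293, chromosome 6, 129461591 to 129472779, - strand), the beta-glucan receptor dectin-1, which the annotation types as a polymorphic pseudogene, rose 29.4-fold (SE 0.444). The chemokine genes Ccl3 (ENSMUSG00000000982, chromosome 11, 83647844 to 83649355, - strand) and Ccl6 rose 27.7-fold (SE 0.406, with 7 counts in WT) and 7.36-fold (SE 0.311). Smaller rises were found for Tlr2, an innate immune receptor (3.77-fold), Cd68, a lysosomal protein of phagocytes (2.87-fold), Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147, + strand), the microglial lipid receptor (2.75-fold, adjusted p = 0.0199), and St14, a membrane serine protease (4.57-fold). Ngfr, the p75 neurotrophin receptor, rose 2.99-fold, with an adjusted p of 0.0465. Kcna1, a voltage-gated potassium channel, Vipr1, a receptor for vasoactive intestinal peptide, and Cacna1i, a T-type calcium channel, fell by 0.691, 0.648 and 0.526 on the log2 scale (SE 0.121, 0.107 and 0.0913). Kcna1, Vipr1 and Cacna1i read 254, 34.6 and 156 CPM in WT and 157, 22.1 and 109 in 5xFAD. They were also low without the transgenes in Tet1(+/-), at 169, 26.3 and 110 CPM, so WT was above every other genotype. In all, 18 genes rose and 3 fell by edgeR, and 2175 genes had an unadjusted p under 0.05.

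Among the lists fixed beforehand, 6 of 32 measured genes of disease-associated microglia rose, 26 did not pass and 23 rose when adjusted over the list alone, with a median log2 change of 0.717 (camera adjusted p = 0.0363 with an estimated correlation). No complement gene of 12 passed over all genes, while 9 rose when adjusted over the list alone. C3ar1, the C3a receptor, and C1qa, a chain of C1q, had log2 changes of 1.44 and 0.944 and adjusted p-values of 0.0565 and 0.0777, and the list's adjusted p was 0.0363 with an estimated correlation. Cholesterol synthesis genes had positive changes in 20 of 20 cases (median 0.272, adjusted p = 0.0238 with an estimated correlation). Of these, Fdps, the farnesyl diphosphate synthase, rose 1.35-fold over all genes tested and 8 rose when adjusted over the list alone. Another 16 lists passed camera with its preset correlation and not with an estimated one. Lysosome genes (0 of 23 over all genes, 12 when adjusted over the list alone, median 0.264) had an adjusted p of 0.096 with an estimated correlation, and cytokine and NF-kB genes (1 of 13, 5 when adjusted over the list alone, median 0.184) one of 0.0852. Reactive astrocyte genes had a median of 0.478 over 16 members, 0 of which passed over all genes and 4 when adjusted over the list alone (adjusted p = 0.197 with an estimated correlation). Gfap, the astrocyte filament protein gene, had a 4.37-fold change with an adjusted p of 0.135. Homeostatic microglia genes (1 of 14, 4 when adjusted over the list alone, median 0.307), antigen presentation (0 of 16, median 0.354) and interferon response (0 of 23, median 0.348) had adjusted p-values of 0.372, 0.392 and 0.537 with an estimated correlation. The homeostatic member that rose was Olfml3, a secreted matrix protein of microglia, at 1.73-fold.

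Lower medians were found for excitatory neuron markers (-0.303 over 14), synaptic genes (-0.125 over 24), immediate-early genes (-0.183 over 20), myelin genes (-0.339 over 17) and the DNA methylation machinery (-0.129 over 18), and no member passed. Their adjusted p-values with an estimated correlation were 0.322, 0.483, 0.662, 0.69 and 0.432. With the ventral forebrain markers, which were high in both 5xFAD libraries, as a covariate, the excitatory neuron median was -0.0332 (adjusted p = 0.55 with the preset correlation) and the synaptic one -0.0465 (0.0975). With striatal and choroid plexus markers as covariates the synaptic median was -0.0654 (adjusted p = 0.25). Immediate-early genes (0.085 and -0.0353) and the DNA methylation machinery (-0.0487 and -0.0853) were not called with the ventral or with the striatal and choroid plexus covariates, and the methylation list not with the sample-number range as a block (-0.0584). The myelin median was 0.0509 with that block (adjusted p = 0.572 with the preset correlation). In that fit WT 3 and WT 4, alone in their range, carried no weight in the comparison. No change in it, in lists or in counts of genes, can therefore be put down to the range itself. Higher medians were found for oligodendrocyte precursor markers (0.153 over 9), hippocampus and thalamus markers (0.399 over 10, 3 when adjusted over the list alone), stress and unfolded protein genes (0.123 over 21, 2 when adjusted over the list alone) and cytosolic ribosome genes (0.143 over 45). With an estimated correlation the adjusted p-values of these 4 lists were 0.577, 0.372, 0.392 and 0.577. The hippocampus and thalamus median was 0.0171 (adjusted p = 0.954 with the preset correlation) with the ventral covariate, which shares the gene Lhx9 with that list. With striatal and choroid plexus covariates the hippocampus and thalamus median was 0.0684 (0.652). The oligodendrocyte precursor median was -0.0726 (0.23) with the ventral covariate and -0.047 (0.821) with striatal and choroid plexus covariates. Choroid plexus markers had a median of 2.94 in 12 of 12 positive members (adjusted p = 0.392 with an estimated correlation), which was 0.31 without 5xFAD 1. Not called by camera were the lists of astrocyte (median 0.106), inhibitory neuron (-0.111), endothelial (-0.0378), mural and fibroblast (0.0884), erythroid (0.329), amyloid and tau processing (-0.0362), oxidative phosphorylation (0.0415) and mitochondrially encoded genes (0.0862). The striatal list had a median of -0.288, a mean of -0.183 and an upward test direction, and was not called.

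The count of 21 genes was 847 without WT 1, 6 without WT 2, 8 without WT 3, 7 without WT 4 and 6 without either 5xFAD library, and 8 with the sample-number range as a block. St14, Tlr2, Ngfr, Trem2, Kcna1, Vipr1, Cacna1i, Olfml3 and Fdps did not pass when WT 2, WT 3, WT 4, 5xFAD 1 or 5xFAD 2 was left out, nor did Cd68 without WT 2, 5xFAD 1 or 5xFAD 2. With the preset correlation, the interferon list had an adjusted p of 0.056 without WT 3 and 0.0508 without 5xFAD 1, and of 0.165 with the sample-number range as a block and 0.339 with the ventral forebrain covariate. The myelin list had adjusted p-values of 0.0708, 0.616, 0.0657 and 0.167 without WT 1, WT 3, 5xFAD 1 and 5xFAD 2. Its median was 0.03 without WT 3. Also not called were oligodendrocyte precursor markers without WT 2, WT 4 or 5xFAD 2 (medians 0.0177, 0.128 and 0.0956), immediate-early genes without the same libraries (-0.0231, -0.0726 and -0.0449) and synaptic genes without WT 2, 5xFAD 1 or 5xFAD 2 (-0.0963, -0.102 and -0.121). The same held for hippocampus and thalamus markers without WT 2, WT 3 or 5xFAD 1 (0.308, 0.473 and 0.265), stress genes without WT 1, WT 3 or 5xFAD 1 (0.0907, 0.0837 and 0.029) and the DNA methylation machinery without WT 3 or 5xFAD 1 (-0.0807 and -0.0443).

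Tet1(+/-) cortex compared with WT (2 against 4 animals) had 0 genes past the threshold by edgeR, with 1579 at an unadjusted p under 0.05 and a lowest adjusted p of 0.259. DESeq2 on the same genes called 57 (21 higher, 36 lower). The authors' deposited table lists 3 at an adjusted p under 0.05. In the authors' deposited table they were Tfcp2l1, a transcription factor (log2 -0.965, SE 0.205), Gse1 (-0.377) and Gsta4, a glutathione transferase (0.451). Myelin genes had negative changes in 17 of 17 members, with a median of -0.581 and 0 past the threshold over all genes (adjusted p = 0.000276 with the preset and 0.994 with an estimated correlation). Mag, the myelin-associated glycoprotein gene, had a log2 change of -0.788 (SE 0.347, adjusted p = 0.533). The list's adjusted p with the preset correlation was 0.0545 without WT 3, the library with the highest Mbp level, at a median of -0.157. With the sample-number range as a block the myelin median was 0.41 and the list was called in the opposite direction (adjusted p = 0.014 with the preset correlation). In that fit WT 3 and WT 4, alone in their range, carried no weight in the comparison. Tet1(+/-) was compared with WT only through FAD/Tet1(+/-) libraries, so the change cannot be put down to the range itself. Immediate-early genes had a median of 0.256 over 20 members, 0 of which passed (adjusted p = 0.0338 with the preset and 0.994 with an estimated correlation). That list was not called without WT 1 (0.184, adjusted p = 0.405), WT 3 (0.125, 0.289) or Tet1(+/-) 2 (0.0338, 0.966). The other 26 lists were not called, among them the DNA methylation machinery, with a median of -0.0961 over 18. Its member Dnmt3a, a de novo DNA methyltransferase, had a log2 change of -0.32 (adjusted p = 0.39). Pvalb, a marker of fast-spiking interneurons, had a log2 change of -0.929 (SE 0.356, adjusted p = 0.469). Median, mean and test of the interferon, cytokine, homeostatic microglia, synaptic, lysosome, erythroid and mitochondrially encoded lists, none of them called, did not share a sign. Without WT 1 the count of 0 became 325. No sample-number range holds both genotypes, so no value within a range can be given.

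In mice labelled Tet1(+/-), the transgenes were followed through FAD/Tet1(+/-) against Tet1(+/-) (4 against 2 animals). Cst7 rose 252-fold (log2 7.97, SE 0.726, adjusted p = 0.00144), Itgax 43.2-fold (SE 0.537) and Ccl3 36.2-fold (SE 0.45). Cst7 had 4 counts in Tet1(+/-) 1 and 2 together, none of them in Tet1(+/-) 2, and 2198 in FAD/Tet1(+/-), a ratio of 269 with a counting interval of 105 to 987. Ccl3 had 5 and 388 counts, a ratio of 37.9 with an interval of 16.1 to 118. Clec7a had 666 counts over the 4 FAD/Tet1(+/-) libraries and 2 over both Tet1(+/-) libraries, a depth-adjusted ratio of 163 with a counting interval of 44.9 to 1350. Ccl6 rose 10.5-fold, St14 8.19-fold, Cd52, a leukocyte surface glycoprotein, 7.01-fold, Capg, an actin-capping protein, 5.13-fold, Tent5c, a poly(A) polymerase, 4.85-fold, and Cd14, a co-receptor for lipopolysaccharide, 4.8-fold. In all 129 genes rose, and Macrod2, a mono-ADP-ribosylhydrolase, fell by 0.388 on the log2 scale (SE 0.0777, adjusted p = 0.0287), with 1407 genes at an unadjusted p under 0.05. Macrod2, St14, Ccl6 and Cd52 overlap other annotated genes, whose strand was not looked up.

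Of the disease-associated microglia list, 15 of 32 members rose over all genes tested and 29 when adjusted over the list alone (median 1.19, adjusted p = 0.00616 with an estimated correlation). Complement genes rose in 6 of 12 cases, 9 when adjusted over the list alone (median 1.47, adjusted p = 0.00616 with an estimated correlation), among them Itgb2, the integrin CD18 (3.07-fold), C1qa (2.92-fold) and C3ar1 (3.57-fold). Interferon response genes rose in 3 of 23 cases, 21 when adjusted over the list alone (median 1.21, adjusted p = 0.0157 with an estimated correlation). The 3 were Ifit3, an antiviral effector (2.5-fold, SE 0.2), its copy Ifit3b (2.13-fold) and Isg15, a ubiquitin-like modifier (4.35-fold). Lysosome genes rose in 9 of 23 cases, 12 when adjusted over the list alone (median 0.351, adjusted p = 0.00616 with an estimated correlation), including Hexa, a lysosomal glycosidase (1.74-fold), and the mannosidase Man2b1 (1.66-fold). Homeostatic microglia genes rose in 4 of 14 cases, 13 when adjusted over the list alone (median 0.787), with Csf1r, the receptor on which microglia depend, at 1.8-fold and Olfml3 at 2.09-fold. Cytokine and NF-kB genes rose in 2 of 13 cases, 7 when adjusted over the list alone (median 0.617), one of them Nlrp3, an inflammasome sensor, at 2.98-fold. These 2 lists had adjusted p-values of 0.0233 and 0.0157 with an estimated correlation.

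Antigen presentation genes rose in 2 of 16 cases, 12 when adjusted over the list alone (median 1.01). B2m, the light chain of MHC class I, rose 2.26-fold and H2-K1, a class I heavy chain, 1.98-fold, and the list's adjusted p was 0.0527 with an estimated correlation. Cholesterol synthesis genes had 0 past the threshold over all genes, with 6 that rose and 1 that fell when adjusted over the list alone (median 0.161, adjusted p = 0.0681 with an estimated correlation). Reactive astrocyte (median 0.33, 6 when adjusted over the list alone), astrocyte (0.197, 2), myelin (0.333, 0), endothelial (0.188, 0) and ribosome genes (0.191, 0) had adjusted p-values of 0.244, 0.297, 0.87, 0.802 and 0.545 with an estimated correlation, and no member passed over all genes. The myelin list was not called without Tet1(+/-) 2, FAD/Tet1(+/-) 1 or FAD/Tet1(+/-) 2 (medians 0.289, 0.193 and 0.292) nor with the sample-number range as a block (0.03, adjusted p = 0.929), nor the endothelial list without Tet1(+/-) 1 or FAD/Tet1(+/-) 3 (0.115 and 0.0866). Median, mean and test of the hippocampus and thalamus, immediate-early and oxidative phosphorylation lists, none of them called, did not share a sign.

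The count of 130 was 5 without Tet1(+/-) 1, 3 without Tet1(+/-) 2 and 71 with the sample-number range as a block. Apart from Thy1, Ccl3, Clec7a and, without Tet1(+/-) 1, Cst7, no gene named for this comparison passed without Tet1(+/-) 1 or Tet1(+/-) 2. Cd14 and Nlrp3 also did not pass without FAD/Tet1(+/-) 3, Nlrp3 not without FAD/Tet1(+/-) 1, and Macrod2, Ifit3b and Isg15 not without FAD/Tet1(+/-) 1, 2 or 3.

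FAD/Tet1(+/-) cortex compared with 5xFAD (4 against 2 animals) asks what the Tet1 genotype changes in mice with the transgenes. By edgeR 0 genes passed, with 1026 at an unadjusted p under 0.05 and a lowest adjusted p of 0.455. DESeq2 called 11 (6 higher, 5 lower), and edgeR on the libraries of these groups alone called 98 (40 higher, 58 lower). The authors' deposited table lists 7 at an adjusted p under 0.05, with Trem2 (log2 0.816, SE 0.181), Mpeg1, a pore-forming protein of macrophages (0.914), Parp14 (1.05) and Rnf213 (0.803), both interferon-inducible, Laptm5, a lysosomal membrane protein (0.723), and Dlg2, a synaptic scaffold (0.245), higher in FAD/Tet1(+/-). Evpl, the desmosomal plakin envoplakin, was the lower gene at that threshold in the authors' deposited table (-1.23, SE 0.226). At an adjusted p under 0.1 the authors' deposited table lists 40 (36 higher, 4 lower).

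Interferon response genes had positive changes in 23 of 23 members, with a median log2 change of 0.816, 0 past the threshold over all genes and 3 when adjusted over the list alone (adjusted p = 0.203 with an estimated correlation and 0.163 with fry). Ifit3 differed by 1.94-fold (log2 0.959, SE 0.191, adjusted p = 0.577), Gbp3, a guanylate-binding protein, by 2.01-fold and Cxcl10, an interferon-induced chemokine, by 3.19-fold. In the lowest sample-number range, with 1 library of each genotype, the mean difference of the list was 0.637, and in the next range, also with 1 of each, it was 0.846. Disease-associated microglia genes had a median of 0.403 (0 of 32, 16 when adjusted over the list alone), with Trem2 at 1.76-fold (SE 0.203, adjusted p = 0.577) and Clec7a at 2.08-fold. Within the same ranges the mean differences of that list were 0.515 and 0.498, and those of homeostatic microglia genes 0.347 and 0.3. Homeostatic microglia (median 0.465, 12 of 14 when adjusted over the list alone), complement (0.505, 6 of 12), antigen presentation (0.504, 5 of 16) and lysosome genes (0.152, 7 of 23) were also called with the preset correlation, with 0 members past the threshold over all genes. With an estimated correlation the adjusted p was 0.206 for disease-associated microglia, homeostatic microglia, complement and lysosome and 0.209 for antigen presentation.

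Immediate-early genes had a median of 0.502 over 20 members, and Egr2, Ier2 and Nr4a1, transcription factors and a regulator induced by neuronal activity, had log2 changes of 1.31, 1.14 and 1.03. Inhibitory neuron markers had a median of -0.188 over 15, with 3 that fell when adjusted over the list alone. The GABA-synthesising enzymes Gad2 and Gad1 had log2 changes of -0.611 and -0.278 and the vesicular GABA transporter Slc32a1 -0.53. Cytokine and NF-kB (median 0.361), excitatory neuron (0.24) and ribosome genes (0.073) were called with the preset correlation as well. The adjusted p with an estimated correlation was 0.352 for immediate-early, cytokine and excitatory neuron genes, 0.241 for inhibitory neuron markers and 0.843 for ribosome genes. The excitatory neuron median was 0.0418 (adjusted p = 0.473 with the preset correlation) with striatal and choroid plexus markers as covariates, 0.0583 (0.803) with the ventral forebrain markers as a covariate and 0.161 (0.0618) with the sample-number range as a block. Choroid plexus markers (-1.21 over 12) and striatal markers (-1 over 12) had adjusted p-values of 0.632 with an estimated correlation, and the choroid plexus median was 1.38 without 5xFAD 1. With the sample-number range as a block, choroid plexus markers (-0.257, adjusted p = 0.136 with the preset correlation) and ribosome genes (0.027, 0.545) were not called. Without 5xFAD 2 the excitatory neuron (adjusted p = 0.176) and ribosome lists (0.657) were not called with the preset correlation, nor was the ribosome list without FAD/Tet1(+/-) 3 (0.877) or the cytokine list without FAD/Tet1(+/-) 1 (0.0589). Median, mean and test of the oligodendrocyte precursor, amyloid and tau processing, and stress lists, none of them called, did not share a sign.

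**Figure D3:**
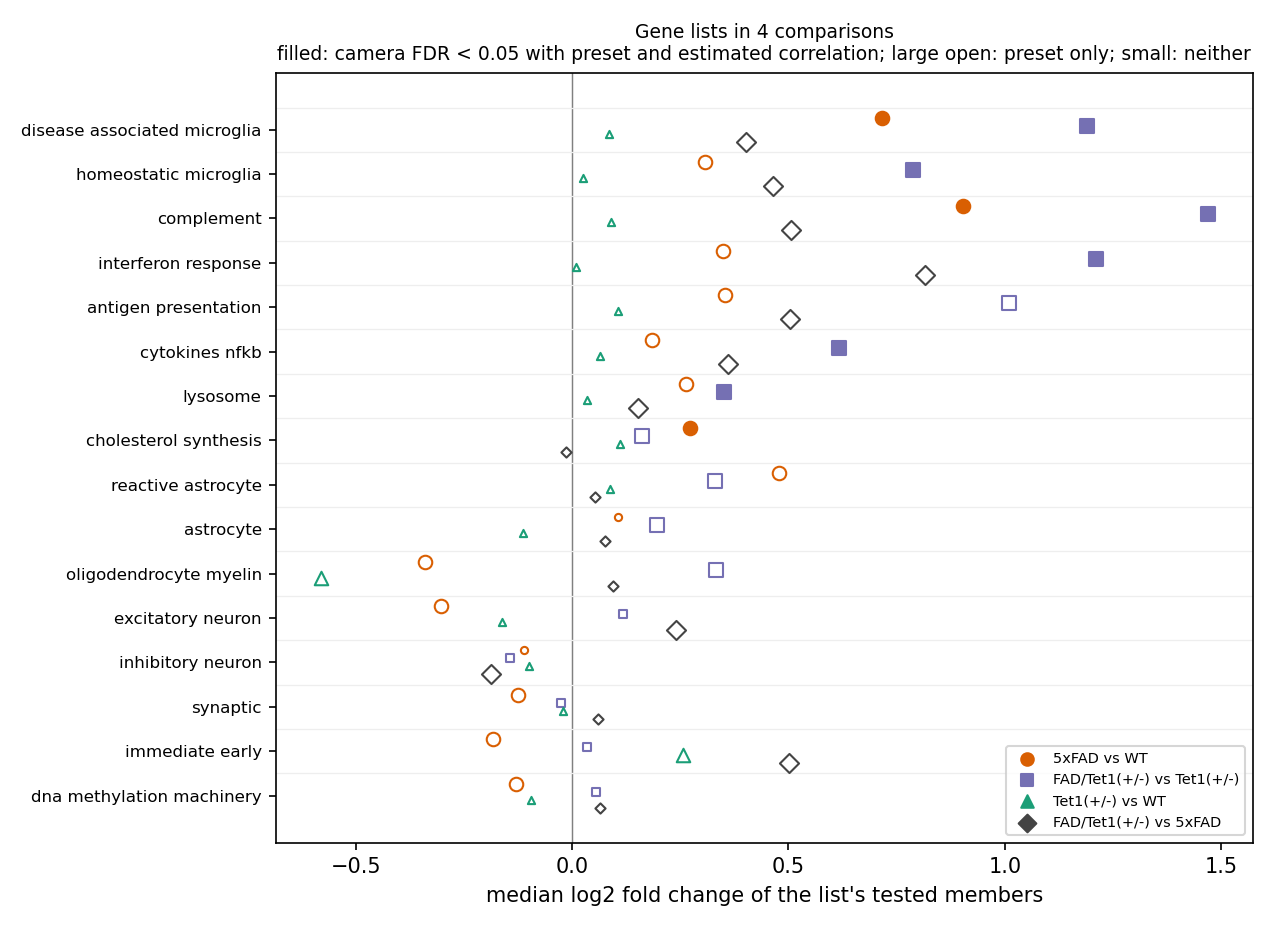
Median log2 fold change (x axis) of the members of 16 gene lists (y axis) in 4 comparisons; filled points passed camera at 0.05 with preset and estimated correlation, large open points with the preset correlation alone, and small points with neither. The interferon list had a median of 0.816 in FAD/Tet1(+/-) against 5xFAD as an open point and of 1.21 in FAD/Tet1(+/-) against Tet1(+/-) as a filled one.

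FAD/Tet1(+/-) against WT (4 against 4 animals) had the most called genes in the main fit, 323 higher and 38 lower, with 2153 at an unadjusted p under 0.05. That rank did not hold with the sample-number range as a block or without WT 1. Cst7 rose 515-fold (log2 9.01, SE 0.582, adjusted p = 3.89e-05, counting interval of the ratio 228 to 2150), Clec7a 61.1-fold, Ccl3 54.9-fold, Itgax 53.6-fold, Ccl6 13.2-fold, St14 9.44-fold and Trem2 4.86-fold. Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912, - strand) rose 6.96-fold (log2 2.8, SE 0.361, adjusted p = 0.00406), and Lyz2, the lysozyme of myeloid cells, 6.89-fold. The largest falls were in Ky, a muscle protease (-1.09), Klhl1, a kelch protein of neurons (-1.04), Lgr5, a Wnt pathway receptor (-1.01), Evpl (-0.892), the serine protease Prss23 (-0.717) and Pdyn, the prodynorphin gene (-0.695). Adamtsl5, Sertad4, Zfhx4 and Kcna1 fell by 0.608, 0.56, 0.533 and 0.498 on the log2 scale. Each gene named here as a fall also had a lower mean in Tet1(+/-), without the transgenes, than in WT. Prss23, Ky and Adamtsl5 read 11.9, 1.87 and 5.71 CPM in Tet1(+/-) and 12.4, 1.55 and 5.88 in FAD/Tet1(+/-). In 5xFAD, with intact Tet1, they read 13.3, 1.9 and 5.62. In WT they read 20.5, 3.31 and 8.97, above every other genotype. Lgr5 and Evpl, by contrast, read 4.11 and 9.09 in 5xFAD against 3.84 and 7.23 in WT. The striatal list, of which Pdyn is not a member although striatal neurons express it, had a median of -1.17 in this comparison and was not called.

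The microglial lists rose, with 24 of 32 disease-associated (29 when adjusted over the list alone, median 1.23), 11 of 14 homeostatic (13, median 0.767) and 8 of 12 complement genes (10, median 1.45) past the threshold over all genes. Their adjusted p-values with an estimated correlation were 0.00336, 0.0136 and 0.00336. Interferon response genes rose in 10 of 23 cases (22 when adjusted over the list alone, median 1, adjusted p = 0.0136 with an estimated correlation), with Cxcl10 at 11.7-fold (8 counts in WT) and Bst2, the virus-tethering protein tetherin, at 3.09-fold. Antigen presentation genes rose in 7 of 16 cases (14, median 1.06) and lysosome genes in 12 of 23 (13, median 0.408), with adjusted p-values of 0.0244 and 0.00463 with an estimated correlation. Cytokine and NF-kB genes rose in 5 of 13 cases (5 when adjusted over the list alone, median 0.384, adjusted p = 0.0125 with an estimated correlation), including Ccl4 at 14.7-fold (6 counts in WT) and Ccl12 at 6.7-fold (9 counts in WT). Cholesterol synthesis genes rose in 5 of 20 cases, and when adjusted over the list alone 14 rose and 1 fell (median 0.276, adjusted p = 0.00799 with an estimated correlation). Fdps, the squalene synthase Fdft1, the methylsterol oxidase Msmo1 and the squalene epoxidase Sqle rose 1.28-fold, 1.24-fold, 1.25-fold and 1.27-fold.

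Reactive astrocyte genes rose in 4 of 16 cases (7 when adjusted over the list alone, median 0.485), namely Gfap, Ggta1, a galactosyltransferase (2.34-fold), Osmr, the oncostatin M receptor (2.18-fold), and Vim, vimentin (1.64-fold). That list's adjusted p was 0.0681 with an estimated correlation. Inhibitory neuron markers had 2 of 15 members that fell, Gad1 (log2 -0.456, SE 0.0704, adjusted p = 0.00229) and Slc32a1 (-0.371, adjusted p = 0.0414), with a list median of -0.164 and an adjusted p of 0.104 with an estimated correlation. Astrocyte markers (median 0.115, 0 of 14, 4 when adjusted over the list alone), oligodendrocyte precursor markers (0.235, 0 of 9), immediate-early genes (0.236, 0 of 20), stress genes (0.092, 1 of 21, 4 when adjusted over the list alone) and ribosome genes (0.212, 1 of 45, 25 when adjusted over the list alone) were called with the preset correlation. The stress gene was Atf3, a stress-induced transcription factor, at 4.16-fold, and the ribosome gene Rpl10a at 1.25-fold. With an estimated correlation the adjusted p-values of these 5 lists were 0.531, 0.531, 0.664, 0.23 and 0.343. The oligodendrocyte precursor list was not called without WT 2 (0.0757), WT 4 (0.16) or FAD/Tet1(+/-) 1 (0.145), nor the immediate-early list without WT 1 (0.206), WT 3 (0.107), FAD/Tet1(+/-) 1 (0.163) or FAD/Tet1(+/-) 4 (0.245). Clu, the extracellular chaperone clusterin, rose 1.36-fold and Homer2, a postsynaptic scaffold, 1.22-fold.

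The count of 361 was 842 without WT 1, 238 without WT 2, 235 without WT 4, 214 without FAD/Tet1(+/-) 3 and 60 with the sample-number range as a block. In the blocked fit WT 3 and 4 and FAD/Tet1(+/-) 3 and 4 carried no weight in this comparison. The lower count can thus not be put down to the range itself. Evpl did not pass without FAD/Tet1(+/-) 3, nor Pdyn without FAD/Tet1(+/-) 1, 3 or 4, Ky without WT 3, WT 4 or FAD/Tet1(+/-) 2 or 3, and Sqle without WT 3, WT 4 or FAD/Tet1(+/-) 1 or 2. Klhl1, Lgr5, Adamtsl5, Sertad4, Zfhx4, Slc32a1, Homer2, Vim and Rpl10a each lost their call in 5 to 7 of the 8 fits without 1 library of these groups.

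Whether the response to the transgenes differed between the Tet1 backgrounds was tested as an interaction. No gene passed by edgeR (0, with 1942 at an unadjusted p under 0.05), and DESeq2 called 100 (54 higher, 46 lower). The lowest adjusted p, 0.0731, was that of Ighm, the immunoglobulin mu heavy chain. Without WT 1 the count was 470, and it was 1 without WT 4 and 1 without FAD/Tet1(+/-) 4. Interferon response genes had positive interaction terms in 23 of 23 members (median 0.857, 4 when adjusted over the list alone, adjusted p = 1e-07 with the preset and 0.853 with an estimated correlation). Among them Ifit3 had a term of 1.2 (SE 0.276) and Xaf1, a pro-apoptotic interferon target, one of 1.65 (SE 0.319), both with an adjusted p of 0.242. Disease-associated microglia (median 0.353), homeostatic microglia (0.45), antigen presentation (0.435), lysosome (0.263), excitatory neuron (0.431) and myelin genes (0.672) were the other lists called with the preset correlation, with 0 members past the threshold over all genes. For each of these 6 lists the adjusted p was 0.853 with an estimated correlation. Antigen presentation was not called without WT 1 (adjusted p = 0.11) or 5xFAD 2 (0.0987), disease-associated microglia, lysosome and excitatory neuron genes not without 5xFAD 2 (each 0.0822), and excitatory neuron genes not without Tet1(+/-) 1 (0.0555). The excitatory neuron term was 0.181 (adjusted p = 0.0765) with striatal and choroid plexus markers as covariates and 0.0262 (0.99) with the ventral forebrain markers as a covariate. The myelin term was -0.0507 (adjusted p = 0.9) with the sample-number range as a block. Median, mean and test of the reactive astrocyte, oligodendrocyte precursor, inhibitory neuron, mural and fibroblast, and stress lists, none of them called, did not share a sign.

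Across genes, 16 rose in both backgrounds, against 0.137 for independent lists of 18 and 129 among 16975. These comparisons share no library. Cst7, Itgax, Clec7a, Ccl3, Ccl6, St14, Tlr2, Cd68, Trem2, Olfml3 and Thy1 were among the 16, with Ptprc, Fcer1g, Ly9, Gpr84 and Gm49339, which were named after their values were seen. No gene fell in both. Ngfr, called in 5xFAD against WT, had a log2 change of -0.229 in FAD/Tet1(+/-) against Tet1(+/-), and Kcna1, Vipr1 and Cacna1i had changes of 0.0905, 0.112 and 0.19 there. Kcna1, Vipr1 and Cacna1i were already low in Tet1(+/-), at 169, 26.3 and 110 CPM against 254, 34.6 and 156 in WT. Over all genes tested, the log2 changes of the backgrounds had a Pearson r of 0.207 and a Spearman rho of -0.072, and over the 13680 genes with an average log2 CPM of at least 1 these were 0.2 and -0.11. The r was 0.0736 without FAD/Tet1(+/-) 1, 0.0911 without 5xFAD 1, 0.1 without Tet1(+/-) 2, 0.0514 without both choroid plexus libraries and 0.094 with the sample-number range as a block, and 0.147 to 0.287 without each other library in turn. The rho was -0.146 to 0.0512 with 1 library left out. Genes are not independent replicates, so no p-value is given. Left-out libraries moved the number of shared genes between 3, without Tet1(+/-) 2, and 68, without WT 1, with 6 without WT 2, 8 without WT 3, 7 without WT 4, 6 without either 5xFAD library, 4 without Tet1(+/-) 1, and 10, 37 and 29 without FAD/Tet1(+/-) 2, 3 and 4.

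**Figure D4:**
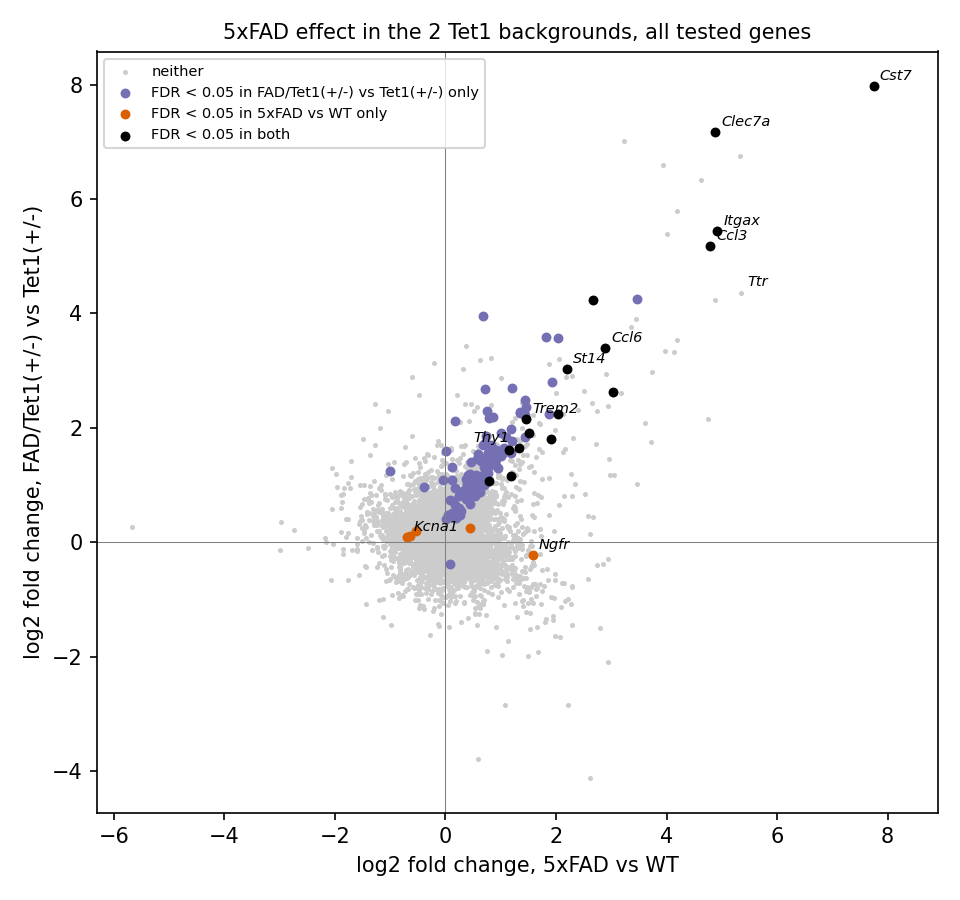
Log2 fold change of each tested gene in 5xFAD against WT (x axis) and in FAD/Tet1(+/-) against Tet1(+/-) (y axis), with genes called in either comparison marked. Cst7 lay at 7.74 and 7.97, Thy1 at 1.34 and 1.64, and 16 genes rose in both.

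The average effect of the transgenes over both backgrounds (6 against 6 animals) held 213 genes that rose and 0 that fell by edgeR, with 1449 at an unadjusted p under 0.05. Cst7 rose 232-fold (SE of the log2 change 0.499), Clec7a 65.1-fold, Itgax 36.1-fold, Ccl3 31.7-fold, Gfap 4.54-fold (SE 0.31), Lyz2 4.16-fold and Capg 3.74-fold. Of the lists, 21 of 32 disease-associated microglia genes (29 when adjusted over the list alone, median 0.941), 8 of 12 complement genes (10, median 1.2), 5 of 14 homeostatic microglia genes (13, median 0.526) and 11 of 23 lysosome genes (12, median 0.269) rose. Cholesterol synthesis (5 of 20, 13, median 0.219), cytokine and NF-kB (5 of 13, 7, median 0.427), interferon response (3 of 23, 16, median 0.768), antigen presentation (3 of 16, 11, median 0.678) and reactive astrocyte genes (3 of 16, 7, median 0.508) rose as well, with the counts adjusted over the list alone given second. For these 9 lists the adjusted p with an estimated correlation ran from 0.0026 to 0.0493. Astrocyte (median 0.135), oligodendrocyte precursor (0.18), synaptic (-0.0631), stress (0.0545) and ribosome genes (0.176) had adjusted p-values of 0.302, 0.484, 0.483, 0.302 and 0.337 with an estimated correlation. Choroid plexus markers, with a median of 2.1, had one of 0.439, and their median was 0.252 without 5xFAD 1 and FAD/Tet1(+/-) 1. The oligodendrocyte precursor median was 0.0711 with the ventral covariate (camera adjusted p = 0.203 with the preset correlation). With striatal and choroid plexus covariates it was 0.135 (0.0848). The myelin list, not called, had a median of -0.00259 and a mean of 0.0178.

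The count of 213 was 353 without WT 1, 110 without 5xFAD 1, 102 without Tet1(+/-) 1, 68 without Tet1(+/-) 2 and 112 with the sample-number range as a block. Gfap did not pass without Tet1(+/-) 1 or Tet1(+/-) 2. The synaptic list was not called without WT 2, WT 4, 5xFAD 1, 5xFAD 2, Tet1(+/-) 1 or FAD/Tet1(+/-) 3 (medians -0.0401, -0.0565, -0.0501, -0.0592, -0.0599 and -0.0492). The stress list was not called without 5xFAD 1 or Tet1(+/-) 2 (0.0373 and 0.0292), nor the oligodendrocyte precursor list without 5xFAD 2 or Tet1(+/-) 2 (0.136 and 0.134).

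The authors' deposited table of 5xFAD against WT held 95 genes at an adjusted p under 0.05 (82 higher, 13 lower), 20 of the 21 called here among them. The authors' deposited table of FAD/Tet1(+/-) against Tet1(+/-) held 272 (261 higher, 11 lower), with 128 of the 130. In the authors' deposited table of Tet1(+/-) against 5xFAD, 21 genes were lower in Tet1(+/-) and 0 higher.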

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

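Of the tests in this part, those on Thy1, choroid plexus and WT 1 were chosen only after the result was seen, as were the alternatives without the choroid plexus libraries and with marker covariates.

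A library far from the others of its group was found for 13 of 200 values by Dixon's test, and chance flags about 1 in 20 groups. FAD/Tet1(+/-) 3 gave 7 of the 13. Its mean log2 of homeostatic microglia genes was 1.15, against 0.58 to 0.67 in the other 3 libraries of the group. It also read App at 1250 CPM (others 1560 to 1630), Thy1 at 2560 (1990 to 2050), Kcna1 at 165 (184 to 187), Selplg, a microglial adhesion ligand, at 59.5 (41 to 43.3), Man2b1 at 94.1 (74.9 to 77) and Bst2 at 7.56 (4.11 to 4.35). FAD/Tet1(+/-) 4 read Zfhx4 at 12.5 CPM (14.9 to 15.2) and Ccl12 at 0.404 (0.96 to 1.12), and FAD/Tet1(+/-) 2 read Homer2 at 111 (117 to 118). Among WT libraries, WT 1 had a mean log2 of hippocampus and thalamus markers of 0.43 (others -0.17 to -0.1), WT 4 read Man2b1 at 39.7 CPM (48.5 to 49.1) and WT 3 read Tapbp, a chaperone of MHC class I, at 21.6 (24.7 to 25.3).

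The interaction test flagged 7 lists as different in response between the Tet1 backgrounds with the preset correlation of camera. Their median interaction terms were 0.857 for interferon response, 0.353 for disease-associated microglia, 0.45 for homeostatic microglia, 0.435 for antigen presentation, 0.672 for myelin (-0.0507 with the number block), 0.431 for excitatory neuron and 0.263 for lysosome genes. With an estimated correlation the adjusted p of each was 0.853, and 0 genes passed by edgeR.

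Interferon genes had a median log2 change of 0.816 in FAD/Tet1(+/-) against 5xFAD, with 23 of 23 members positive, 0 of 23 past the threshold over all genes, and a list test that passed with the preset correlation alone. Choroid plexus tissue, striatal tissue and sample-number range were weighed as technical explanations. The median was 0.972 without the choroid plexus libraries, which leaves 5xFAD 2 alone in its group. It was 1.04 with marker covariates. With the number block it was 0.761, and there only FAD/Tet1(+/-) 1 and 2 share a range with a 5xFAD library. No median fell as far as these explanations predict, but with so few 5xFAD animals this argues only weakly against each. Ventral forebrain markers were not weighed. Their mean was 1.629 and 2.058 in the 5xFAD libraries and -0.203 to 1.144 in FAD/Tet1(+/-), so they separate these groups too. A higher dose of the transgenes is not excluded, and the values went the way it predicts. The median Thy1 level of FAD/Tet1(+/-), 2030 CPM, was above the highest 5xFAD value of 1710, as was each of its libraries (1990 to 2560). An effect of the Tet1 genotype may contribute as a hypothesis, but with 2 animals in 5xFAD and adjusted p-values of 0.203 with an estimated correlation and 0.163 with fry, it stays open.

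Choroid plexus markers were high in 5xFAD 1 and FAD/Tet1(+/-) 1, with scores of 3.839 and 3.39. An effect of the 5xFAD genotype is argued against by the other 4 libraries with the transgenes, whose median was 0.356 log2 above that of the 6 without. Choroid plexus tissue in these samples was not tested apart from the markers that showed the pattern, and stays open.

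Ventral forebrain markers were higher in WT 1 (1.544) than in the other WT libraries (-0.781 to -0.283), and no biological explanation was tested. The score of WT 1 lay among those of 5xFAD (1.629 and 2.058) and Tet1(+/-) (1.599 and 0.881). FAD/Tet1(+/-) ran from -0.203 to 1.144. The level of these markers is thus in part confounded with genotype in comparisons with WT. It also separates FAD/Tet1(+/-) from 5xFAD, since both 5xFAD scores lay above every FAD/Tet1(+/-) score. Fits without WT 1 rest on the low WT libraries alone. Of the 7 markers whose values had not been seen when the list was written, 6 were higher in WT 1 than in each other WT library, which is consistent with tissue from beside the neocortex. Of the 219 genes at least 1 log2 unit away in WT 1, chromosome 1 held the most, at 8.8%, which argues against 1 large genomic segment of another strain. Smaller genomic differences are not excluded, since Eno1b read 36 CPM in WT 1 and 1.02 to 1.31 in the other WT libraries, and over all 12 was high in the 7 with the highest ventral scores (0.636 to 2.058, others at most 0.121), so the explanation stays open.

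A pair of predictions on the myelin list was set aside after its leave-one-out values had been seen, so its values are given without weighing. Other groupings of the libraries were refitted for the comparisons with the most calls. For FAD/Tet1(+/-) against WT, 1 of 35 splits, the real one, had as many genes (361, highest other 34). That is the smallest share 35 splits can give, so chance is made less likely and is not excluded. For the average 5xFAD effect, 3 of 100 splits had as many as the real 213, and the highest other had 446. Splits with 446 and 400 genes both set WT 1, WT 3, 5xFAD 1, 5xFAD 2 and FAD/Tet1(+/-) 3 on the same side. The striatal scores of WT 1, WT 3, 5xFAD 1 and 5xFAD 2 were 1.202, 2.255, 0.904 and 0.708. Those of WT 2 and WT 4 were -1.716 and -1.742. The immediate-early scores were -0.345, -0.437, -0.104 and -0.288 against 0.434 and 0.348. FAD/Tet1(+/-) 1, on that side in the split with 400, went the other way in both, with -0.937 and 0.566. Whether these scores account for the calls was not tested. Alleles carried with the targeted Tet1 locus were looked for among 104 genes within 10 Mb of Tet1. Of these, 1.92% had an unadjusted p under 0.05 for the average Tet1 effect by edgeR. The 95th percentile was 7.69% over windows of as many genes across the genome, the region of Tet1 included.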

How the results depend on the processing

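The omission of the choroid plexus libraries, the marker covariates and the ventral forebrain covariate were chosen only after the results were seen. For each changed value below the cause was not tested, beyond fewer libraries where some were left out.

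Among 149 results of named and targeted genes, 149 kept their direction and side of the threshold with DESeq2, 148 with its size factors, 146 without a filter, 141 with the replicate block, 127 with marker covariates, 124 with the ventral covariate, 99 without the choroid plexus libraries and 79 with the number block. The 149 are results of named genes past the threshold in the main fit, with Thy1, and with Tet1 apart from the interaction and the average effect. Other named genes that did not pass, App among them, were not counted. DESeq2 called more genes than edgeR in each comparison, so the 149 kept with it say little. In fits to the compared groups alone 85 of 109 results were kept. With 1 library left out 990 of 1250 were kept. Among 84 list calls, 84 were kept with the size factors of DESeq2, 80 with the replicate block, 75 with the number block, 26 with an estimated correlation and 34 with fry, and 605 of 666 with 1 library left out.

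The 21 genes of 5xFAD against WT were 41 at a threshold of 0.1, 58 without a filter, 47 with the replicate block, 8 with the number block, 5 without the choroid plexus libraries, 8 with marker covariates, 3 with the ventral covariate and 227 with DESeq2, of which 50.7% were higher against 85.7%. A fit to these groups alone had 15, all higher, of which 9 are among the 21. Of the 8 with the number block 5 are among the 21, and of the 47 with the replicate block 19. They were 6 to 847 with 1 library left out. Tet1(+/-) against WT, at 0, had 2 without a filter, 1 with the replicate block, 3 with marker covariates, 57 with DESeq2 and 0 to 325 with 1 library left out. The 130 of FAD/Tet1(+/-) against Tet1(+/-) were 199 at 0.1, 71 with the number block, 60 without the choroid plexus libraries, 206 with marker covariates, 232 with DESeq2 and 3 to 167 with 1 library left out. FAD/Tet1(+/-) against 5xFAD, at 0, had 1 without a filter, 1 with the ventral covariate, 11 with DESeq2 and 98 in a fit to these groups alone. The 361 of FAD/Tet1(+/-) against WT were 552 at 0.1, 553 with the replicate block, 60 with the number block, 201 without the choroid plexus libraries, 551 with marker covariates, 558 with DESeq2 (78.3% higher against 89.5%) and 214 to 842 with 1 library left out. The interaction, at 0, had 1 gene at 0.1, 100 with DESeq2 and 0 to 470 with 1 library left out. The average effect of 213 was 112 with the number block, 69 without the choroid plexus libraries and 68 to 353 with 1 library left out. The 16 genes higher in both backgrounds were 40 with the replicate block, 5 with the number block, 5 without the choroid plexus libraries, 7 with marker covariates, 3 with the ventral covariate and 3 to 68 with 1 library left out.

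The number of lists called in 5xFAD against WT was 19, and it was 3 with an estimated correlation, 5 with fry, 11 with the ventral covariate and 13 to 21 with 1 library left out, where lists outside the 19 can be among them. In Tet1(+/-) against WT it was 2, with 0 under an estimated correlation, 0 under fry, 8 under the ventral covariate and 0 to 5 with 1 library left out. FAD/Tet1(+/-) against Tet1(+/-) had 13, then 6 and 8. FAD/Tet1(+/-) against 5xFAD had 13, then 0 and 0. FAD/Tet1(+/-) against WT had 15, then 8 with an estimated correlation. The interaction had 7, then 0 and 0, with 12 under the replicate block, 12 under the ventral covariate and 6 to 12 with 1 library left out. The average effect had 15, then 9 with an estimated correlation.

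The direction of the test turned for 9 list results. Myelin in 5xFAD against WT was 0.0509 with the number block and -0.466 to 0.03 with 1 library left out. With the number block, myelin in Tet1(+/-) against WT was 0.41 and called in the opposite direction (adjusted p = 0.014), and in the interaction it was -0.0507. With the ventral covariate, oligodendrocyte precursor and immediate-early genes in 5xFAD against WT were -0.0726 and 0.085, and excitatory neuron genes in the interaction 0.0262. Immediate-early genes in Tet1(+/-) against WT ran from 0.0338, in the fit that turned, to 0.486 with 1 library left out. Choroid plexus markers ran from -2.92 to 1.38 in FAD/Tet1(+/-) against 5xFAD, and were -0.0208 for the average effect with marker covariates. Those covariates include the mean of these same markers, so the last turn carries no information. Among uncalled targeted genes, Tet1 was 0.0327 in Tet1(+/-) against WT and 0.0595 in FAD/Tet1(+/-) against WT with the number block, and -0.0949 to 0.00256 in the latter with 1 library left out. In FAD/Tet1(+/-) against 5xFAD, Tet1 was -0.0287 without the choroid plexus libraries and -0.00213 to 0.131 with 1 library left out. Thy1 in Tet1(+/-) against WT was -0.151 with the number block and -0.0126 to 0.0803 with 1 library left out.

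The labels do not say that replicate numbers pair the samples, and not every pair correlated over 0.1, so the numbers were not used as pairs and pairing stays undecided. The 14 same-number pairs correlated at -0.0305 to 0.283, 7 of them over 0.1, and 6 of 12 libraries correlated best with their own number. The 10 pairs in the same sample-number range correlated at -0.0801 to 0.283. Depth was not varied. On simulated data at the depth and group sizes of these libraries, 7.46%, 46.3% and 75.8% of interactions of 1.5-fold, 2-fold and 4-fold were recovered. Those data had no correlation between genes and no difference in tissue.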

Other observations

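The gene copies below were found by a scan made only after the values were seen, and no explanation was tested. The levels of a pair of gene copies did not follow the genotypes. Eno1b (ENSMUSG00000059040, chromosome 18, 48045335 to 48048412, + strand), a copy of the enolase gene Eno1, read 35.4 to 39.2 CPM in WT 1, both 5xFAD, both Tet1(+/-) and FAD/Tet1(+/-) 1 and 2, and 1.02 to 1.98 in the other 5 libraries. BC002163 (ENSMUSG00000081824, chromosome 16, 42955631 to 42955949, + strand), a processed pseudogene of Ndufs5, a subunit of respiratory complex I, read 19.3 and 20.4 CPM in WT 3 and WT 4 and 2.78 to 5.52 in the others. Ndufs5 itself read 32.8 and 33.1 in WT 3 and WT 4 and 44.2 to 54.4 in the others. Ndufs5 and BC002163 together read 52.1 and 53.5 in WT 3 and WT 4, within the 47 to 59.9 of the others. Eno1 and Eno1b together read 487 to 550 in the libraries with high Eno1b and 488 to 570 in the other 5. The sums thus did not differ between the sets of libraries.

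The average effect of the Tet1 genotype over both transgene states held 0 genes past the threshold by edgeR, with 741 at an unadjusted p under 0.05. Arc, an activity-induced synaptic gene, read 53.5, 195, 59.1 and 191 CPM in WT 1 to 4. Baiap3, a vesicle trafficking protein of hypothalamus, read 37 CPM in WT 1 and 2.79 to 9.52 in the other WT libraries. Dlk1, a Notch ligand, read 21.3 in WT 1 and 0.695 to 2.78 in the other WT libraries.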
